A study of Glycine max with 12 samples.

How the data were processed

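Root RNA of soybean HN89 was sequenced in 12 libraries, 3 for each combination of low or high Mg with no inoculation or Rhizophagus irregularis. Per the labels, total RNA was purified with CTAB-PBIOZOL and ethanol precipitation and made into libraries with the BGI RNA-Seq kit. The deposited expected_counts are expected counts, that is reads per gene estimated by the authors from their alignments before the files were deposited, without scaling between libraries. They also give FPKM computed by the authors, in which the smallest listed value was 0.01, so that genes below it in a library are not listed. The submitters' processing notes name Bowtie2, HISAT, RSEM and DESeq2; their versions and roles are not given in the sources used here. Gene identifiers carry the Wm82.a2.v1 suffix. The reference gene table is of another build, so no coordinates were used; symbols such as PHT1-12 were taken from it through the protein accession of each gene's deposited description (29614 genes matched, 1212 of them to a named symbol).

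Counts of genes not listed in a library were set to 0 (76024 gene and library pairs). Of 50012 genes listed in any library, 37487 were listed in all 12. Totals were 21.6, 21.8 and 21.3 M counts in LMg_NM, 20.9, 21.2 and 21.4 in LMg_AM, 20.7, 21.8 and 21.8 in HMg_NM and 20.8, 20.4 and 19.6 in HMg_AM, with 42278 to 44624 genes listed. The 50 most abundant genes took 7.2 to 11.66% of a library. Levels below 1 CPM rest on few counts. Folds against a group without counts are lower bounds, taken against a floor of 3 counts over the group.

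Expected counts were rounded and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) after TMM normalization (factors 0.864 to 1.112) and filterByExpr, which left 38351 genes. All 12 libraries entered 1 fit of the 4 group means, without a block, by the quasi-likelihood method, and 7 comparisons were drawn from it: inoculation at low Mg, at high Mg and on average, high against low Mg without inoculation, with it and on average, and the interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.415 and correlations between libraries of a group were 0.847 to 0.956. The comparison of inoculation at low Mg and that of Mg levels in inoculated roots share the LMg_AM libraries, so they are not independent. The labels do not say whether a replicate is a plant, a pot or a pool; p-values measure the spread between these samples.

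Gene lists (36, written as patterns before the data were examined and matched to the deposited descriptions, which are informative for 26187 genes) were tested with camera at a preset correlation of 0.01, with the correlation estimated per list, and with fry. Annotation terms with 15 to 500 tested genes (250 terms) were tested by camera for the 2 average comparisons. Genes are named by a rule written before the data were examined: per comparison, the 6 called genes with the largest rise and the 6 with the largest fall, among genes whose compared libraries do not overlap (a share of 10% by chance for 3 against 3), with a mean of at least 5 CPM in the higher group and an informative description; per list and comparison, up to 4 called members of lowest p; and, for mycorrhiza markers and magnesium transporters, the 4 of highest level.

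Alternatives were RLE size factors, library size only, no low-count filter, a filter of 50 counts in 3 libraries, a 2-fold threshold, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with 1 or 0.1 added, replicate number as a block, only the libraries of the compared groups, and each library left out in turn. Robust dispersion, library size only for the lists, and leaving out 2 libraries in doubt were added after the data had been seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

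The procedure was tested on simulated data with 50 genes changed at each fold. The changed genes were drawn from those above a minimum mean count, so recovery of weaker genes was not measured. Genes were simulated independently, without states shared by the genes of a library. In the comparison at low Mg, edgeR recovered 2% of 2-fold, 44% of 4-fold, 78% of 8-fold and 96% of 16-fold changes, with 3 false calls of 113; for the interaction it recovered 0, 14, 52 and 72%, with 4 false calls of 73. DESeq2 made 70 to 108 false calls of 189 to 280 on the same data, so its counts are given as an alternative only.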

Results

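Roots of soybean HN89 were compared at low and high magnesium supply (LMg and HMg), each without inoculation (NM) and with the arbuscular mycorrhizal fungus Rhizophagus irregularis (AM), with 3 libraries per group. Levels are mean CPM (counts scaled to the size of the library times its TMM factor) ± SD over the 3 libraries of a group. Inoculation set the libraries apart more than Mg supply did. On the first principal component of log2 CPM (42.6% of the variance), the 6 NM libraries lay between -152.8 and -38.5 and 5 of the 6 AM libraries between 97.2 and 135.9. The remaining library, replicate 3 of LMg_AM, lay at -13.6, and at -152.2 on the second component (18.6%).

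**Figure D1:**
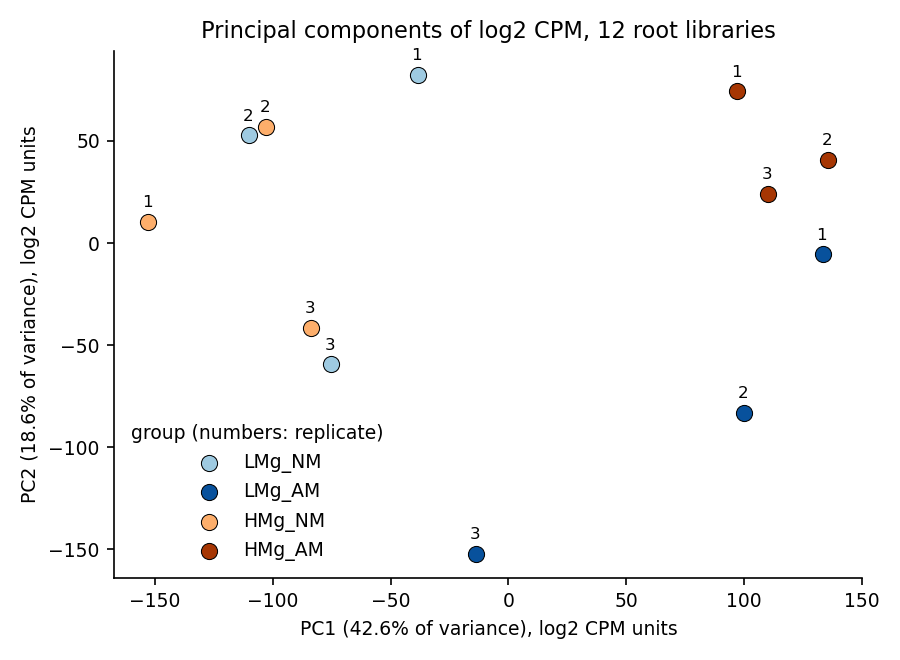
Each point is 1 of the 12 root libraries on the first 2 principal components of log2 CPM (x axis, 42.6% of the variance; y axis, 18.6%), coloured by group and numbered by replicate. NM libraries lie at or below -38.5 on the x axis, and replicate 3 of LMg_AM lies apart from the other 2 LMg_AM libraries, which are at 133.5 and 99.9.

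At low Mg, inoculated roots held more transcripts of the mycorrhizal programme and fewer of phosphate transport and of the response to phosphate starvation. The palmitoyl-acyl carrier protein thioesterase Glyma.20G122900, of the family whose member FatM makes fatty acids for the fungus in other legumes, rose from 0.508 ± 0.595 CPM in LMg_NM to 17.0 ± 5.72 in LMg_AM (n = 3 each; log2 fold change 5.03, edgeR quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.00735). Without replicate 1 of LMg_NM, which held marker transcripts, the log2 fold change was 6.65. The U-box protein 50 gene Glyma.18G147800 stood at 40.2 ± 15.2 CPM in LMg_AM, against 2 counts in total over the LMg_NM libraries (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00057). Germin-like protein 9-2 (Glyma.20G119800) rose from 3.94 ± 3.71 to 194 ± 89 CPM, and cellulose synthase A subunit 3 (Glyma.06G316700) from 1.46 ± 0.734 to 10.9 ± 3.09 (log2 fold changes 5.62 and 2.89, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00604 for each). The former was 6.73 without replicate 1 of LMg_NM. Of the 7 mycorrhiza marker genes, 4 rose and 3 did not pass; 5 rose adjusted over the list alone (median log2 fold change 3.58, camera adjusted p = 0.000123, adjusted p = 0.677 with an estimated correlation).

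Most of the phosphate transporter and phosphate-starvation genes that passed at low Mg fell. The phosphate transporter PHT1-6 (Glyma.10G186400) fell from 6.34 ± 1.01 to 0.516 ± 0.059 CPM (log2 fold change -3.60, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00606). Enzymes that replace phospholipids when phosphate is short fell as well: monogalactosyldiacylglycerol synthase 2 (Glyma.17G108700) from 266 ± 50 to 49.6 ± 17.3 CPM and non-specific phospholipase C4 (Glyma.03G092800) from 44.5 ± 14.2 to 4.17 ± 0.92 (log2 fold changes -2.42 and -3.41, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00933 and 0.00789). Of 28 phosphate transporter genes, 9 fell, 2 rose and 17 did not pass. Adjusted over the list alone, 15 fell and 4 rose (median log2 fold change -0.91, camera adjusted p = 9.53e-05, adjusted p = 0.628 with an estimated correlation). Of 77 phosphate-starvation genes, 16 fell, 1 rose and 60 did not pass. Of them, 28 fell and 3 rose adjusted over the list alone (median -0.41, camera adjusted p = 4.02e-06, adjusted p = 0.628 with an estimated correlation). The transporter genes that rose were PHT1-13 (Glyma.13G040200), from 6.12 ± 5.8 to 73.6 ± 16.9 CPM, and PHT1-12 (Glyma.14G123500), from 6.84 ± 10.4 to 326 ± 105 (log2 fold changes 3.58 and 5.57, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0162 and 0.0322). PHT1-13 did not pass without replicate 2 of LMg_NM or of LMg_AM (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.074 and 0.0528). PHT1-12 did not pass without replicate 2 of LMg_NM, replicate 1 or 2 of LMg_AM, replicate 2 of HMg_NM, or replicate 1 or 3 of HMg_AM (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0809, 0.0693, 0.087, 0.0503, 0.0515 and 0.0503). Without replicate 1 of LMg_NM, the log2 fold changes of PHT1-13 and PHT1-12 were 4.71 and 8.62. The starvation gene that rose was SPX domain protein 2-like Glyma.10G261900, from 2.90 ± 1.17 to 20.8 ± 7.29 CPM (log2 fold change 2.83, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00864). Summed over the 77 genes, the LMg_AM libraries held 2513 to 4607 CPM, against 7442 to 9411 in LMg_NM, 7082 to 9886 in HMg_NM and 4121 to 6179 in HMg_AM, so that each AM library lay below each NM library at both Mg levels.

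**Figure D2:**
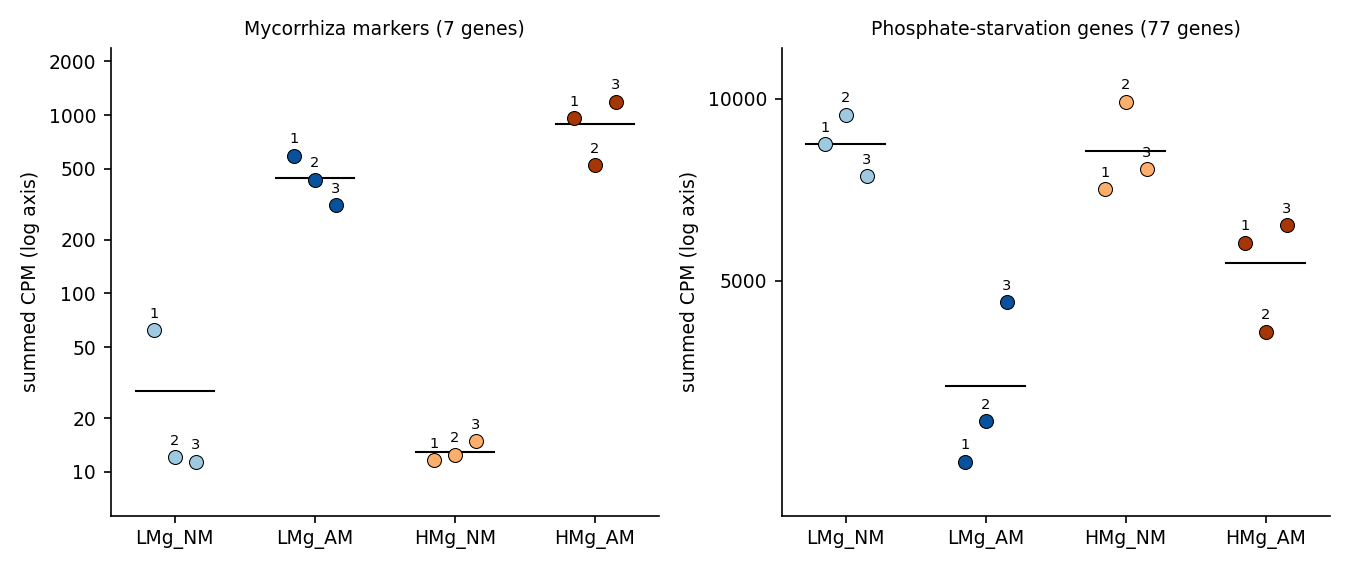
Points are single libraries (numbers: replicate), lines are group means, and the y axis is the CPM summed over the 7 mycorrhiza marker genes (left) or the 77 phosphate-starvation genes (right), on a log axis. Marker sums are 313 to 1188 CPM in the AM libraries and 11.4 to 14.8 in the NM libraries other than replicate 1 of LMg_NM, which is at 62.2; the starvation genes are at 2513 to 4607 in LMg_AM, 4121 to 6179 in HMg_AM and 7082 or more in the NM libraries.

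Other genes with a high level in uninoculated roots also fell at low Mg. The external alternative NAD(P)H-ubiquinone oxidoreductase Glyma.06G298300 fell from 14.2 ± 4.96 to 0.112 ± 0.0154 CPM (log2 fold change -6.90), the sulfate transporter 2.1-like gene Glyma.08G138600 from 47.1 ± 7.32 to 4.85 ± 1.58 (-3.28), and the sugar transport protein 5-like gene Glyma.06G103900 from 21.7 ± 5.60 to 1.29 ± 0.706 (-4.08, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.000337, 0.00581 and 0.00663). Germin-like protein Glyma.16G060700, among the abundant transcripts of NM roots, fell from 594 ± 159.5 to 20.7 ± 6.93 CPM (log2 fold change -4.84, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00346). In all, 697 of 38351 genes were called higher and 696 lower. This count was 799 without replicate 1 of LMg_NM, 308 without its replicate 2, 616, 295 and 2273 without replicates 1, 2 and 3 of LMg_AM, and 882 and 839 without replicates 1 and 3 of HMg_AM. It was 991 to 1881 without any other library. In a fit of the LMg_NM and LMg_AM libraries alone, without the spread of the HMg groups, 58 genes were called. Of the 115 gene entries named for this comparison, 39 kept their call in each of the 12 fits without 1 library, those given above among them, except PHT1-12 and PHT1-13.

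The lists of photosynthesis and heat-shock genes were called higher in LMg_AM as well. Of 38 nuclear photosynthesis genes, which roots express weakly, 5 rose, 0 fell and 33 did not pass by edgeR's quasi-likelihood test with Benjamini-Hochberg. Adjusted over the list alone, 13 rose (median log2 fold change 1.98, camera adjusted p = 1.13e-09, adjusted p = 0.628 with an estimated correlation). Their sum was 106, 179 and 395 CPM in the LMg_AM libraries, 68.7, 80.5 and 127 in LMg_NM, 58.6 to 66.4 in HMg_AM, and 129, 64.4 and 75.1 in HMg_NM, so the sums overlap. Of 226 heat-shock and chaperone genes, 7 rose, 1 fell and 218 did not pass. Among these, 7 rose and 0 fell adjusted over the list alone (median 0.43, camera adjusted p = 0.00032, adjusted p = 0.917 with an estimated correlation). This median was 0.27 without replicate 1 of LMg_NM and 0.83 without its replicate 3. The 17.3 kDa class I heat shock protein gene Glyma.14G063800 rose from 19.0 ± 8.26 to 2326 ± 2341 CPM (log2 fold change 6.93, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00917, and 0.0505 without replicate 2 of LMg_NM). The log2 fold change was 5.69 without replicate 2 of LMg_AM, the library of highest level.

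**Figure D3:**
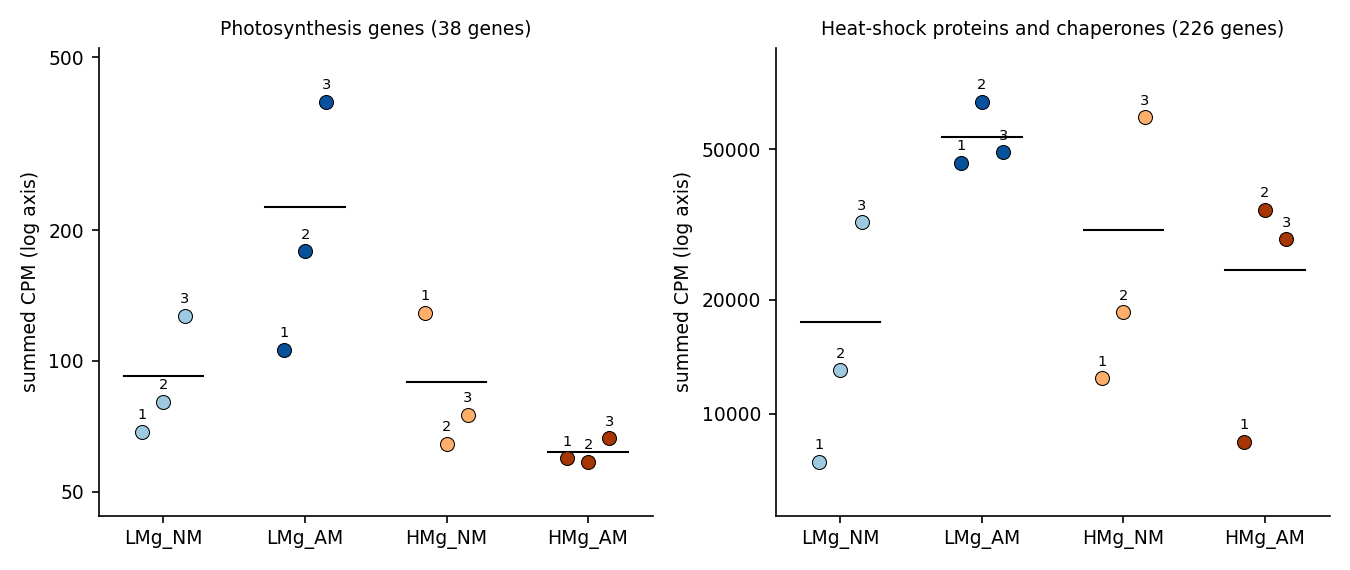
Points are single libraries (numbers: replicate), lines are group means, and the y axis is the CPM summed over 38 photosynthesis genes (left) or 226 heat-shock and chaperone genes (right), on a log axis. The LMg_AM libraries hold 106 to 395 CPM of the photosynthesis genes against 58.6 to 66.4 in HMg_AM and 64.4 to 129 in HMg_NM, and 46066 to 66849 CPM of the heat-shock genes, a range that replicate 3 of HMg_NM (60853) also reaches.

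At high Mg, inoculation raised the phosphate transporter genes PHT1-12 and PHT1-13 and some genes of fatty acid synthesis. The phosphate transporter PHT1-12 (Glyma.14G123500), described as 1-11-like, the class that carries phosphate from the fungus in other plants, rose from 0.861 ± 0.427 CPM in HMg_NM to 660.4 ± 260.3 in HMg_AM, and PHT1-13 (Glyma.13G040200) from 3.85 ± 1.09 to 145 ± 61.8 (n = 3 each; log2 fold changes 9.57 and 5.23, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00355 and 0.00207). The thioesterase Glyma.20G122900 rose from 0.215 ± 0.0606 to 26.7 ± 9.92 CPM, the biotin carboxyl carrier protein Glyma.19G028800 from 5.61 ± 0.795 to 102 ± 19.6, and malonyl CoA-acyl carrier protein transacylase Glyma.11G164500 from 2.28 ± 0.552 to 36.6 ± 7.52 (log2 fold changes 6.92, 4.18 and 4.0, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0011, 0.00122 and 0.00101). Serine carboxypeptidase II-3-like Glyma.13G028500 rose from 2.60 ± 1.5 to 1665 ± 337 CPM (log2 fold change 9.32, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00105). With no count in any HMg_NM library, the mavicyanin-like gene Glyma.19G114300 (121 ± 39.0 CPM in HMg_AM) was at least 2460-fold higher and the neutral ceramidase-like gene Glyma.13G076400 (60.6 ± 28.7) at least 1230-fold higher, against a floor of 3 counts over the group (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00973 and 0.013). The carotenoid isomerase D27 gene Glyma.03G158000, at the entry to strigolactone synthesis, rose from 16.8 ± 3.08 to 45 ± 7.06 CPM (log2 fold change 1.42, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00431).

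By list, 28 of 87 fatty acid and lipid supply genes rose at high Mg, 0 fell and 59 did not pass by edgeR's quasi-likelihood test with Benjamini-Hochberg. Adjusted over the list alone, 31 rose and 1 fell (median log2 fold change 0.95, camera adjusted p = 2.54e-10, adjusted p = 0.349 with an estimated correlation). Of 181 protease and germin genes, 39 rose, 3 fell and 139 did not pass. Of them, 68 rose and 8 fell adjusted over the list alone (median 0.98, camera adjusted p = 1.26e-09, adjusted p = 0.349 with an estimated correlation). Of 349 cell wall genes, 13 rose and 2 fell, shares no larger than those of all genes (1464 and 421 of 38351). Adjusted over the list alone, 24 rose and 4 fell (median 1.22, camera adjusted p = 3.87e-10, adjusted p = 0.349 with an estimated correlation). Of 252 histone and cell division genes, 17 rose and 1 fell. Among these, 68 rose and 3 fell adjusted over the list alone (median 1.11, camera adjusted p = 9.23e-09, adjusted p = 0.408 with an estimated correlation). Kinesin KP1-like Glyma.14G011100 is an example, from 0.553 ± 0.163 to 4.96 ± 0.872 CPM (log2 fold change 3.15, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00241). Of 54 gibberellin genes, 15 rose and 0 fell. Adjusted over the list alone, 23 rose and 1 fell (median 0.86, camera adjusted p = 1.64e-06, adjusted p = 0.349 with an estimated correlation). They include the DELLA gene Glyma.19G096400, from 1.67 ± 0.899 to 68.6 ± 22.5 CPM (log2 fold change 5.34, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00339).

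The lists of xylem and lignin genes and of endodermis and suberin genes were also called higher at high Mg (medians 1.42 and 1.08, camera adjusted p = 2.86e-07 and 4.07e-07, adjusted p = 0.447 and 0.349 with an estimated correlation). In the first, 7 of 156 genes rose and 1 fell (21 and 4 adjusted over the list alone), among them caffeoyl-CoA O-methyltransferase Glyma.08G103900 from 1.25 ± 0.548 to 15.9 ± 4.62 CPM. The 7 of 156 are near the share of all genes called higher (1464 of 38351). In the second, 10 of 125 rose (12 adjusted over the list alone), among them CASP-like protein 4D1 Glyma.09G170100, at 25.8 ± 8.05 CPM in HMg_AM and 0.0154 ± 0.0267 in HMg_NM. The phosphate transporter and phosphate-starvation lists were not called at high Mg: medians were -0.43 and -0.16 but means 0.27 and 0.22 (camera adjusted p = 0.102 and 0.888). In all, 1464 genes were called higher and 421 lower. The count was 849 and 942 without replicates 1 and 2 of HMg_NM, 1084, 1058 and 887 without replicates 1, 2 and 3 of HMg_AM, and 4024 without replicate 3 of LMg_AM, which adds to the shared estimate of spread only. It was 1564 to 2728 without any other library. In a fit of the HMg_NM and HMg_AM libraries alone, 4041 genes were called. Of the 120 gene entries named for this comparison, 78 kept their call in each of the 12 fits without 1 library, those given here among them.

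Averaged over both Mg levels, inoculation raised 5 of the 7 mycorrhiza marker genes, and 0 fell (5 and 0 adjusted over the list alone, median log2 fold change 4.41, camera adjusted p = 2.18e-06, adjusted p = 0.596 with an estimated correlation). PHT1-12 (Glyma.14G123500) stood at 326 ± 105 CPM in LMg_AM and 660.4 ± 260.3 in HMg_AM, against 6.84 ± 10.4 and 0.861 ± 0.427 in the NM groups (log2 fold change 7.57, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.000608). The NM level of 6.84 is carried by replicate 1 of LMg_NM; without it the log2 fold change was 9.09. The glutamate receptor 2.5 gene Glyma.16G061700 had no count in the 6 NM libraries and was at least 213-fold higher in AM roots (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.000283). The ammonium transporter AMT4.3 (Glyma.19G244400) rose on average (log2 fold change 6.39, and 9.25 without replicate 1 of LMg_NM, the only LMg_NM library in which it had counts), and the phosphate transporter PHT1-10 (Glyma.20G204100) fell from 19.9 ± 5.19 and 13.6 ± 2.87 CPM in LMg_NM and HMg_NM to 1.02 ± 1.16 and 1.5 ± 1.07 in the AM groups (-3.74, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.000832 and 0.00122). Of the 28 phosphate transporter genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone, median -0.72, camera adjusted p = 0.000886, adjusted p = 0.596 with an estimated correlation). Of 32 blue copper and early nodulin-like genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone, median 1.08, camera adjusted p = 6.51e-06, adjusted p = 0.596 with an estimated correlation). In all, 2758 genes were called higher and 2361 lower.

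That count of 5119 was 9780 without replicate 3 of LMg_AM, 3264 and 2759 without its replicates 1 and 2, 2646 without replicate 2 of LMg_NM, 2922 and 2805 without replicates 1 and 2 of HMg_NM, and 2638 and 2944 without replicates 2 and 3 of HMg_AM. It was 3773 to 5535 without any other library. Of 250 annotation terms, 28 passed for the average over Mg, among them fatty acid metabolic process (91 genes), microtubule-based process (51), lignin metabolic process (21) and cellulose synthase activity (20), all higher (camera adjusted p = 5.83e-07, 1.64e-05, 0.000148 and 0.000153, adjusted p = 0.987 with an estimated correlation for each). The inoculation effects at low and high Mg, which share no library, correlated across the 38351 genes with r = 0.601 and rho = 0.451, and genes are not independent replicates. Both comparisons called 465 genes higher, where 26.6 would be shared by independent lists, and 103 lower, where 7.6 would be; 2 genes were called in opposite directions. Leaving out replicate 1 of LMg_NM gave r = 0.721, and leaving out replicate 1 of LMg_AM r = 0.427, the range over the 12 libraries.

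Mg supply alone changed no gene past the threshold in uninoculated roots. Magnesium transporter MRS2-3 (Glyma.01G242000), the magnesium transporter gene of highest level in these roots, stood at 162 ± 27 CPM in LMg_NM and 182 ± 42.9 in HMg_NM. By edgeR's quasi-likelihood test with Benjamini-Hochberg, 0 of 38351 genes passed, with 1712 at an unadjusted p under 0.05. The latter is less than a share of 0.05 of the genes tested. Of the other tools, limma-voom and limma on log2 FPKM also gave 0, and DESeq2 gave 114. At this size a test on simulated changes recovered 30% of genes with a 4-fold change and 88% of those with an 8-fold change. Smaller differences were thus mostly not detectable. The simulated changes were made only in genes above a minimum mean count, so recovery of weaker genes was not measured. By camera, the list of 134 WRKY genes was called higher at high Mg (median log2 fold change 0.41, adjusted p = 3.78e-09) and that of 36 sulfate transport and assimilation genes lower (median -0.40, adjusted p = 0.000255), with 0 genes of either list passing alone or adjusted over the list alone (adjusted p = 0.809 for both with an estimated correlation). The WRKY median was 0.06, 0.21 and 0.74 without replicate 3 of HMg_NM, replicate 2 of LMg_NM and replicate 3 of LMg_NM, and the sulfate median -0.22 without replicate 1 of LMg_NM.

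In inoculated roots, high Mg went with more transcripts of several genes that were low in LMg_AM. Ribonuclease 1-like Glyma.02G107900, a phosphate-starvation gene, rose from 0.921 ± 0.203 CPM in LMg_AM to 9.96 ± 1.09 in HMg_AM, against 2.36 ± 0.159 in LMg_NM and 2.26 ± 0.635 in HMg_NM (n = 3 each; log2 fold change 3.43, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00751). The sulfate transporter 2.1-like gene Glyma.08G138600 rose from 4.85 ± 1.58 to 56.3 ± 29.7 CPM and the trypsin inhibitor gene Glyma.08G341300 from 0.806 ± 0.0493 to 5.21 ± 0.87 (log2 fold changes 3.54 and 2.68, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0148 and 0.0113). The sulfate transporter gene did not pass without replicate 2 or 3 of LMg_AM or replicate 1 of HMg_AM (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.136, 0.0718 and 0.0643), nor did the trypsin inhibitor gene without replicate 2 or 3 of LMg_AM (0.0971 and 0.0741). Of the 38 photosynthesis genes, 0 passed over all genes and 24 fell adjusted over the list alone (median log2 fold change -2.22, camera adjusted p = 1.47e-15, adjusted p = 0.312 with an estimated correlation). Of the 77 phosphate-starvation genes, 1 rose. Of them, 24 rose and 1 fell adjusted over the list alone (median 0.45, camera adjusted p = 6.29e-07, adjusted p = 0.312 with an estimated correlation). Of 33 carotenoid and strigolactone genes, 0 passed over all genes. Adjusted over the list alone, 13 rose and 1 fell (median 0.66, camera adjusted p = 1.4e-05, adjusted p = 0.312 with an estimated correlation).

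In all, 23 genes were called higher and 5 lower at high Mg in inoculated roots, with 6346 at an unadjusted p under 0.05. That balance did not hold in every setting: higher and lower were 41 and 29 with library size only, 113 and 144 with a replicate block, 1171 and 1231 in DESeq2, and 214 and 325 without replicate 1 of LMg_AM. The count of 28 rested on single libraries: it was 44, 17 and 167 without replicates 1, 2 and 3 of LMg_NM, 539, 2 and 2 without those of LMg_AM, 17 and 17 without replicates 1 and 3 of HMg_NM, and 7, 11 and 14 without those of HMg_AM; without replicate 2 of HMg_NM it was 19. In a fit of the LMg_AM and HMg_AM libraries alone, 0 genes were called. Averaged over inoculation, 8 genes were called higher and 2 lower, with 3870 at an unadjusted p under 0.05. The 6346 and 3870 genes are each more than a share of 0.05 of the genes tested, but genes are not independent replicates. That count of 10 was 3, 0 and 0 without replicates 1, 2 and 3 of LMg_NM, 0 and 1 without replicates 2 and 3 of LMg_AM, 0 and 1 without replicates 2 and 3 of HMg_NM, 0 without each HMg_AM library, 11 without replicate 1 of LMg_AM and 7 without replicate 1 of HMg_NM. None of the 5 gene entries named for the average kept its call in all 12 of these fits. Caffeic acid O-methyltransferase Glyma.07G048800 is 1 of them, at 16.7 ± 9.89 and 51.7 ± 11.5 CPM in LMg_NM and LMg_AM and 1.24 ± 0.23 and 5.25 ± 4.03 in HMg_NM and HMg_AM (log2 fold change -3.52, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0434, and up to 0.183 without 1 library). Of 145 phenylpropanoid and flavonoid genes, 0 passed over all genes. Among these, 10 rose and 0 fell adjusted over the list alone (median 0.40, camera adjusted p = 1.87e-10, adjusted p = 0.486 with an estimated correlation). Of 250 annotation terms, 37 passed, among them photosystem II (22 genes), lower, and glucose catabolic process (76), higher (camera adjusted p = 4.05e-06 and 5.88e-08, adjusted p = 0.731 with an estimated correlation for each).

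The effect of inoculation was not shown to differ between Mg levels for any single gene. PHT1-12 (Glyma.14G123500) had an interaction of 4.0 on the log2 scale (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.385), which rested on replicate 1 of LMg_NM and was 0.94 without it. The sulfate transporter 2.1-like gene Glyma.08G138600, which fell at low Mg, had an interaction of 3.68 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.195). For ribonuclease 1-like Glyma.02G107900 it was 3.50, for PHT1-6 (Glyma.10G186400) 2.09, and for the 17.3 kDa heat shock protein Glyma.14G063800 -3.65 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.107, 0.331 and 0.355). The last was -2.36 without replicate 2 of LMg_AM. Of 38351 genes, 0 passed by this test, with 4236 at an unadjusted p under 0.05. The latter is more than a share of 0.05 of the genes tested, but genes are not independent replicates. Of the other tools, limma-voom gave 0, limma on log2 FPKM 1 and DESeq2 611. Without replicate 3 of HMg_NM, 1 gene passed.

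By camera, 21 of 36 lists differed between Mg levels in their response to inoculation. The effect at high Mg minus that at low Mg was positive for 18 and negative for 3. With an estimated correlation 0 lists differed, and 0 by fry. The sign does not say at which level the response was stronger. Phosphate transporters, with a positive value, fell more at low Mg (medians -0.91 and -0.43 at low and high Mg). WRKY genes, with a negative value, were called lower at high Mg. Photosynthesis genes had a median interaction of -2.01 (38 genes; 0 passed over all genes, 16 lower adjusted over the list alone, camera adjusted p = 3.94e-12, adjusted p = 0.362 with an estimated correlation). Fatty acid and lipid supply genes had a median of 0.88 (87 genes; 0 passed over all genes, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.26e-09, adjusted p = 0.362 with an estimated correlation). Phosphate-starvation genes had a median of 0.76 (77 genes; 0 passed over all genes, 1 higher adjusted over the list alone, camera adjusted p = 3.28e-07, adjusted p = 0.362 with an estimated correlation).

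**Figure D4:**
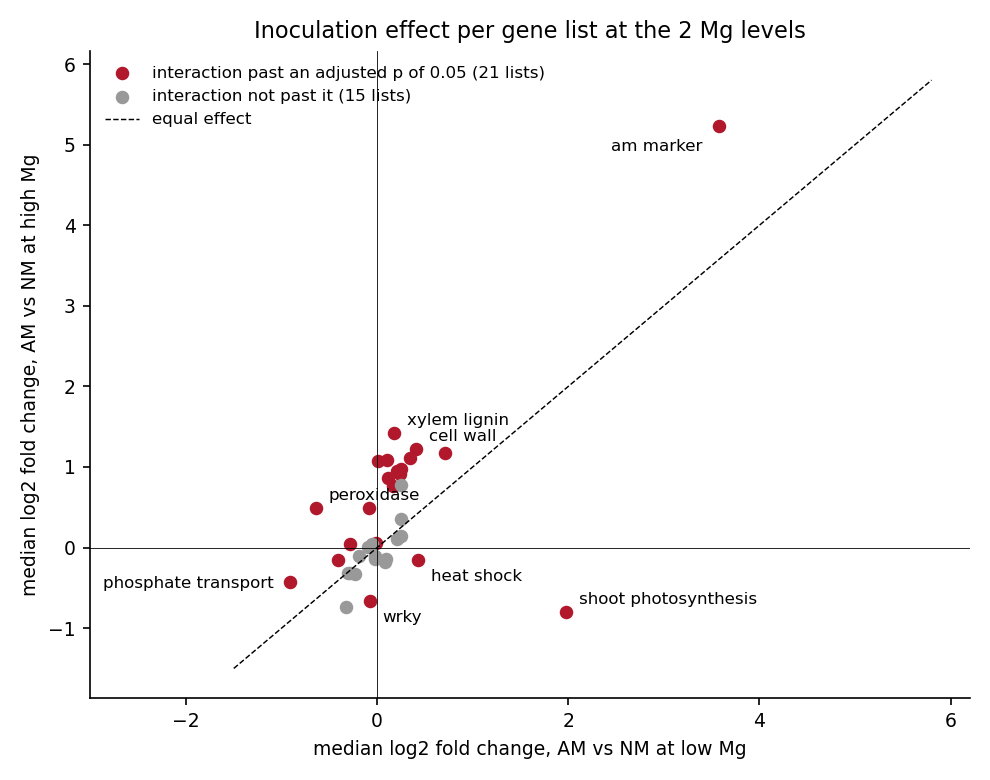
Each point is 1 of 36 gene lists, placed by its median log2 fold change for inoculation at low Mg (x axis) and high Mg (y axis); red marks the 21 lists whose interaction passed in camera with the preset correlation, none of which passed with an estimated one. The mycorrhiza markers lie at 3.58 and 5.23, and the photosynthesis genes at 1.98 and -0.80.

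No magnesium transporter gene passed for Mg supply, and a few passed for inoculation. MRS2-3 (Glyma.01G242000) stood at 162 ± 27, 173 ± 78.3, 182 ± 42.9 and 104 ± 3.37 CPM in LMg_NM, LMg_AM, HMg_NM and HMg_AM, with an interaction of -0.91 on the log2 scale (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.486), which was -0.47 without replicate 3 of LMg_AM. MRS2-4-like Glyma.05G168200 stood at 32.5 ± 1.83, 31.2 ± 4.15, 34.9 ± 5.86 and 30.3 ± 3.34 CPM. Of the 30 genes on the list, 0 passed in any comparison of Mg levels, where camera gave adjusted p = 0.565, 0.519 and 0.796 in NM roots, in AM roots and on average. A small response is not excluded, since these comparisons recovered 0, 2 and 28% of simulated 2-fold changes. For inoculation, the list as a whole was not called either (camera adjusted p = 0.275, 0.985 and 0.526 at low Mg, at high Mg and on average), with a median of -0.19 and a mean of 0.31 at low Mg. Averaged over Mg, 2 genes rose and 1 fell (2 and 0 adjusted over the list alone). MRS2-F (Glyma.15G005200) is 1 of the 2: it had no count in the 6 NM libraries and stood at 4.29 ± 2.36 CPM in LMg_AM and 1.75 ± 1.71 in HMg_AM (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00301). The 1 that fell, NIPA6 (Glyma.06G159100, log2 fold change -0.70, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0462), kept its call only in the fits without replicate 3 of LMg_NM or replicate 3 of LMg_AM. Without each other library its adjusted p was 0.0572 to 0.112 (edgeR quasi-likelihood with Benjamini-Hochberg).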

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

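The counts of other splits of the samples, and the tests of explanations in the paragraphs on marker, photosynthesis and heat-shock transcripts, were chosen only after the results were seen; the interaction test was planned.

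The test of the difference between Mg levels singled out 21 gene lists whose response to inoculation was not the same at low and high Mg. Their medians (effect at high Mg minus effect at low Mg, log2) were -2.01 for photosynthesis, -0.54 for heat shock and -0.53 for WRKY genes. They were 2.31 for mycorrhiza markers, 1.11 for peroxidases, 1.06 for nodule markers, 0.98 for xylem and lignin, 0.89 for proteases and germins, 0.88 for fatty acid and lipid supply, 0.81 for endodermis and suberin, 0.76 for phosphate starvation and 0.74 for cell wall genes. They were 0.69 for histones and cell division, 0.68 for gibberellin, 0.67 each for nitrate uptake and assimilation, phosphate transporters and blue copper proteins, 0.61 each for defence and for carotenoids and strigolactones, 0.40 for flavonoids and 0.39 for seed storage. These calls are by camera with its preset correlation; with an estimated correlation the adjusted p was 0.362 to 0.535 and 0 lists passed, and 0 passed by fry.

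Several of these medians rest on single libraries. Without replicate 1 of LMg_NM they were 0.94 for mycorrhiza markers, 0.31 for cell wall, 0.42 for endodermis, 0.23 for nitrate, 0.58 for nodule markers, 0.57 for proteases, 0.73 for peroxidases, 0.39 for blue copper and 0.12 for xylem genes, the last no longer called (adjusted p = 0.0943). Without replicate 3 of LMg_NM they were -0.85 for heat shock, -0.93 for WRKY, 0.63 for peroxidases, 0.17 for flavonoids (adjusted p = 0.07), 0.26 for blue copper (0.0749) and 0.54 for seed storage (0.0569). Without replicate 3 of HMg_NM they were -0.22 for heat shock, -0.07 for WRKY and 0.43 for seed storage (0.0774). Without replicate 3 of LMg_AM they were -0.11 for WRKY, 0.47 for blue copper (0.121), 0.32 for flavonoids (0.122) and 0.35 for seed storage (0.108). Without replicate 1 of LMg_AM they were -0.81 for WRKY, 0.61 for phosphate transporters (0.0934), 0.68 for blue copper (0.0822) and 0.36 for flavonoids (0.151). Without replicate 2 of LMg_AM they were 1.5 for xylem, 0.71 for flavonoids and 0.78 for seed storage, and without replicate 2 of LMg_NM -0.32 for WRKY. Blue copper was also not called without replicate 1 or 2 of HMg_NM or replicate 2 of HMg_AM (0.0827, 0.065 and 0.122), nor flavonoids without replicate 2 of HMg_NM (0.124); seed storage was at 0.66 and 0.64 without replicate 1 of HMg_NM and replicate 3 of HMg_AM. Without both replicate 1 of LMg_NM and replicate 3 of LMg_AM, the lists of mycorrhiza markers, cell wall, WRKY, blue copper, seed storage, flavonoid and xylem genes were not called (adjusted p = 0.0623 to 0.733).

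Inoculation-induced transcripts were present in 1 uninoculated library, replicate 1 of LMg_NM. Checked were genes called higher by inoculation at high Mg, with a mean of at least 10 CPM in LMg_AM. They also stayed under 0.5 CPM in the other uninoculated libraries. All 111 such genes had counts in replicate 1 of LMg_NM, at a median of 8.31% of the LMg_AM mean (10th to 90th percentile 4.3 to 15.15). Summed over the 7 mycorrhiza marker genes fixed beforehand, that library held 62.2 CPM, against 11.4 to 14.8 in the other uninoculated libraries. The median of 8.31% argues against a wrong label on a library with marker levels like those of LMg_AM. An inoculated root of low colonisation under the wrong label would not be told apart by it. Replicate 3 of LMg_AM, at 56.7% of the other 2 LMg_AM libraries (45.6 to 68.9), argues against an exchange of that library with replicate 1 of LMg_NM. The best mixture of the 6 inoculated libraries left a dispersion of 15, where 1 is sampling noise, which argues against reads carried over from them alone. Low colonisation of that root, or RNA from a sample outside this series, stays open and may explain it; neither was tested.

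The photosynthesis list was called higher in LMg_AM than in LMg_NM, with a median log2 fold change of 1.98 over 38 genes. A single library as the cause is argued against, since the list stayed called and higher in 3 of the 3 fits without 1 LMg_AM library (medians 2.22, 2.0 and 1.75; camera adjusted p = 4.39e-14, 1.04e-10 and 0.000247; 0.628 with an estimated correlation, the highest of all alternatives). Shoot material mixed into the roots is not settled: 53 shoot markers outside the plastid had a median of 0.06, but roots also express 27 of them at 5 CPM or more, so a small share would not show, and the abundant Stem 28 kDa glycoprotein gene stood at 134.8 CPM in LMg_AM against 140.2 in LMg_NM and the stem 31 kDa glycoprotein gene Glyma.08G200100 at 63.91 against 33.86, while another stem 31 kDa gene, Glyma.07G014500, stood at 13.99 CPM in LMg_AM against 0.4363 (log2 fold change 4.99, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.0763). Of the 53, 3 were called: hydroxypyruvate reductase Glyma.10G281400 (0.2009 to 4.005 CPM) and serine hydroxymethyltransferase 3 Glyma.08G274400 (0.1218 to 0.6146) higher, and EPIDERMAL PATTERNING FACTOR-like 2 Glyma.11G044700 (0.639 to 0.04762) lower. Shoot material and a response of the roots to inoculation at low Mg cannot be told apart with these genes, and the second was not tested.

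The heat-shock list was called higher in LMg_AM than in LMg_NM, with a median log2 fold change of 0.43 over 226 genes. A single LMg_AM library as the cause is argued against, since the list stayed called in 3 of the 3 fits without 1 (medians 0.44, 0.45 and 0.40; camera adjusted p = 0.000316, 0.00106 and 0.0114; 0.917 with an estimated correlation, the highest of all alternatives), although it was not called without both replicate 1 of LMg_NM and replicate 3 of LMg_AM (0.16). A state of single libraries that occurs outside LMg_AM too is a candidate explanation. In summed level, 1 of the 9 other libraries (replicate 3 of HMg_NM) reached the lowest LMg_AM library. Summed levels spanned 4.1, 4.9 and 4.3-fold within HMg_AM, HMg_NM and LMg_NM but 1.45-fold within LMg_AM. By the median log2 deviation of the 226 genes from their mean over all libraries, the lowest LMg_AM library was at 0.17. Replicate 3 of HMg_NM (0.27), replicate 3 of LMg_NM and replicate 2 of HMg_AM (0.19 each) lay above it. The remaining libraries outside LMg_AM lay below it. A response to inoculation at low Mg, and conditions shared by these plants at harvest, stay open and untested.

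Other splits of the same samples were tested for each count of genes. For inoculation at low Mg and high Mg and for Mg in uninoculated and inoculated roots, the 10 splits are too few for a share under 0.05: the real splits gave 1393, 1885, 0 and 28 genes, and the highest other split 0 in each case, so that 1, 1, 10 and 1 splits gave as many. For the average inoculation effect (5119 genes), 2 of 100 splits gave as many, the real one included. The other gave 6991. That other split exchanged replicate 1 of LMg_NM with replicate 3 of LMg_AM, the library with marker transcripts and the one apart from its group, and kept the other 10 libraries apart by inoculation, so its count includes most of the real contrast. That it exceeds the real count points to a structure of the samples in LMg. For the average Mg effect (10 genes), 4 of 100 splits gave as many, and the highest other gave 1038, many times the real count. It set replicates 1 and 2 of LMg_NM and 2 of HMg_NM against replicate 3 of LMg_NM and 1 and 3 of HMg_NM, the order of the second principal component, but it also set the 3 LMg_AM against the 3 HMg_AM libraries, with the labels reversed, as did the next highest, with 216 and 11 genes. The count points to a structure of the samples that joins the Mg contrast in inoculated roots to a division of the uninoculated ones, and it cannot be credited to either alone. The share of 4 in 100 does not make the 10 genes a Mg effect. For the interaction (0 genes), 100 of 100 splits gave as many, which a real count of 0 fixes in advance, so this share decides nothing. The highest other gave 1038. It is the split with 1038 genes for the average Mg effect, with the LMg_AM and HMg_AM labels exchanged, so it adds no separate evidence. The splits were first drawn 30 times, with 2, 4 and 30 as large; the number was raised to 100 after that was seen, and only the larger number gives shares under 0.05 for the 2 averages. Their weight is therefore small.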

How the results depend on the processing

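Robust dispersion, library size only for the gene lists, and leaving out both libraries in doubt (replicate 1 of LMg_NM and replicate 3 of LMg_AM) were chosen only after the data had been seen; the other alternatives were planned. Where a value moved, the cause was not tested unless it is given here. Of the 393 named entries, 393 kept direction and call with DESeq2 and with RLE size factors, 389 with robust dispersion, 381 without a low-count filter, 380 with library size only, 376 and 363 on log2 FPKM with 0.1 and 1 added, 351 with limma-voom and 346 without both libraries in doubt; 364 of the 364 that the strict filter tests kept them, and 136 of 243 in fits of the compared groups only. None of these reversed. Of 103 list calls, 102 were the same with RLE size factors and 95 with library size only; fatty acid and lipid supply at low Mg was lost with RLE (adjusted p = 0.0542). Library size only moved the median of all genes to 0.103 for inoculation at high Mg, -0.131 and 0.138 for Mg in uninoculated and inoculated roots and 0.259 for the interaction, against -0.067, -0.007, 0.02 and 0.016 with TMM, and the changes reported are relative to the latter.

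Counts of genes moved as follows. DESeq2 gave 4019, 5660 and 9182 for inoculation at low Mg, at high Mg and on average. It gave 114, 2402 and 846 for Mg without inoculation, with it and on average, and 611 for the interaction. On simulated data it made more false calls than edgeR, but those data were drawn with the spread that edgeR estimated. For Mg in inoculated roots, library size only gave 70 genes, limma-voom 186, log2 FPKM with 1 and 0.1 added 638 and 228; limma-voom gave 0 for Mg on average, and both FPKM settings 1 for the interaction. Fits of the compared groups only gave 58 and 4041 for inoculation at low and high Mg and 0 for Mg in inoculated roots. Only the groups' spread enters, and 4041 is a rise. Without both libraries in doubt, counts were 4179 for inoculation at high Mg, 9077 on average and 0 for Mg in inoculated roots and on average; lists called were 16 for inoculation at low Mg and 18 for Mg on average, and the ribosomal protein list was no longer called, with medians turned to -0.12 for Mg in inoculated roots and -0.06 for Mg on average (camera adjusted p = 0.193 and 0.481). With an estimated correlation, 0 lists were called in each of the 7 comparisons, by construction a test that allows for the genes of a list moving together. Fry called 3, 13 and 10 lists for inoculation at low Mg, at high Mg and on average, 0, 4 and 0 for Mg without inoculation, with it and on average, and 0 for the interaction.

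Replicate block: with replicate number as a block, 257 genes passed for Mg in inoculated roots and 20 for Mg on average, and 102 of 103 list calls and 354 of 393 named entries were the same (fatty acid and lipid supply at low Mg was lost, adjusted p = 0.0703). The pairing check did not settle whether that block is warranted. Of 18 pairs of libraries with the same number, 8 correlated above 0.1 after group means were removed (-0.20 to 0.45, median 0.06, against -0.04 for different numbers). The highest, 0.45, joined replicate 3 of LMg_NM and of HMg_NM, and a pair of different numbers reached 0.41. Of 12 libraries, 6 correlated best on average with those of their own number.

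Leaving out 1 library at a time, counts of genes ranged from 295 to 2273 for inoculation at low Mg, 849 to 4024 at high Mg, 2638 to 9780 on average, 0 to 0 for Mg without inoculation, 2 to 539 with it, 0 to 11 on average, and 0 to 1 for the interaction; the libraries are named with the counts above. Lists called ranged from 7 to 14 at low Mg, 15 to 19 at high Mg, 16 to 19 on average, 6 to 16, 14 to 21 and 7 to 18 for Mg, and 18 to 22 for the interaction. Lists at low Mg were 14 and 13 without replicate 1 of LMg_NM and 3 of LMg_AM; for Mg without inoculation 16 and 15 without replicates 2 and 3 of LMg_NM, and 6 without replicate 1; for Mg on average 18 and 7 without replicates 1 and 2. The correlation across genes of the inoculation effects ranged from 0.427 to 0.721. Of 1236 list results, 1143 were the same, 90 were not called and 3 turned in the direction of camera without being called, all of the ribosomal protein list. In 6 of the 90 the median alone changed sign: ribosomal protein without replicate 2 of HMg_AM (-0.13 for Mg in inoculated roots, -0.02 on average), peroxidases for inoculation at low Mg without replicate 3 of LMg_NM (0.10, against -0.64, and 0.10 without both libraries in doubt), proteases for Mg on average without replicate 3 of LMg_AM (-0.01), and heat shock for Mg without inoculation and WRKY for Mg on average without replicate 3 of HMg_NM (-0.05 and -0.01). The median of ribosomal protein ranged from -0.03 to 0.50 for inoculation on average, from -0.13 to 0.83 for Mg in inoculated roots and from -0.05 to 0.45 for Mg on average. It turned to -0.03 without replicate 1 of LMg_AM in the first, and to -0.12 and -0.05 without its replicate 3 in the others (camera adjusted p = 0.358, 0.226 and 0.747). Of 4716 results of named entries, 3888 kept their call and 0 reversed. Depth was even (19.6 to 21.8 M counts), so it limits weak genes more than comparisons.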

Other observations

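The lists in this part were fixed before the data were examined, and their tests were planned. Of the 36 gene lists, 12 were called in none of the 7 comparisons by camera with its preset correlation. The lowest adjusted p over the comparisons was 0.0574 for sugar transport and metabolism (149 genes, inoculation on average), 0.0581 for ethylene and jasmonate (264, Mg on average), 0.0639 for phloem (10, inoculation on average), 0.095 for ammonium transporters (13, Mg on average), 0.0982 for auxin response (161, interaction) and 0.102 for CBL and CIPK calcium signalling (48, inoculation at high Mg). It was 0.116 for aquaporins (38, Mg on average), 0.176 for iron and zinc uptake (65, inoculation at low Mg), 0.217 for proton ATPases (31, Mg in uninoculated roots), 0.239 for the common symbiosis pathway (29, Mg in uninoculated roots), 0.271 for cation transport (124, Mg on average) and 0.275 for magnesium transporters (30, inoculation at low Mg).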
